A study of Trichoderma reesei with 12 samples.

How the data were processed

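The data are counts per gene in 12 libraries of Trichoderma reesei mycelium. Per the labels' protocols, total RNA was extracted with a kit for plant RNA, and libraries were made with a stranded kit after depletion of ribosomal RNA. The submitters' processing notes name HISAT2 version 2.2.1, a read aligner. The deposited count table holds whole numbers, 1 column per library, and the name of the table refers to featureCounts, a program that counts reads per gene. The genome build, the annotation, the strand setting and the version of the counting program are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart, and how reads shared by near-identical genes were counted is open.

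The table has 10879 rows, of which 10876 carry an identifier made of Tr, a letter from A to G, digits and a W or C, and 3 carry names of the mating type locus mat1-1. Of the gene lengths, 94.7% (10301 rows) are multiples of 3, as coding lengths are; the rest are not. In 388 rows no library had a count. None of the identifiers matched the 9116 genes of the reference table of gene names (0 matches), and no genome was used. The 31 gene lists fixed before the data were examined (such as the SOR cluster, cellulases and light receptors) could therefore not be matched to rows, and no list was tested.

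Groups were taken from the titles and the treatment labels, which give the strain, light or darkness, and a replicate number. The treatment protocol of every sample speaks of darkness, also for the libraries whose title and treatment label give light; the title and treatment label were followed. No label says that a replicate number marks a shared culture or day.

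Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, with TMM normalization (which scales libraries by a trimmed mean of log ratios), the default filter on low counts by group, and the quasi-likelihood F test in 1 fit of 4 group means over all 12 libraries. Of the rows, 8939 passed the filter, and they held at least 99.97% of the counts of each library. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and a second count also required a fold change of at least 2. Contrasts compared sor4 with ku80 in darkness and in light, light with darkness in each strain, and the difference of the strain effects. The common biological coefficient of variation was 0.193. CPM values use the TMM-scaled library sizes and are given as mean ± SD. Ratios of pooled counts have 95% exact binomial intervals; where a group had 0 counts, the ratio was computed against a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Total counts ran from 7844524 to 12027855 per library.

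With no gene names at hand, the rule fixed before the data were examined named, in each direction, the 2 genes with the largest log2 fold change among called genes with at least 5 CPM in the higher group and no overlap between groups; other named genes are said to be chosen after their values were seen. The scripts were tested on simulated counts with the means, dispersions and depths of these libraries. In them 200 genes were changed, 100 by 2-fold and 100 by 4-fold. More changed genes make the adjusted p less strict, so the test would find a smaller share where few genes change. In these tests the share of false calls was 8.33% for sor4 against ku80 in darkness and 2.80% in light, 4.48% for light against darkness in ku80 and 4.71% in sor4, and 2.88% for the difference of effects.

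Alternatives were median-of-ratios size factors, library size alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, a stricter filter (at least 5 CPM in at least 2 libraries), only the groups compared, the replicate number as a block, each library left out in turn, and the 20 most abundant genes left out. Since ku80 has no replicate 3 or 4, the fit with the block compared the strains directly only within replicates 1 and 2. A robust estimate of the dispersion was added after the data were seen. Splits of the libraries into other groups of the same sizes were counted as well.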

Results

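Gene expression was measured by RNA sequencing in mycelium of Trichoderma reesei, a filamentous fungus used for the production of cellulases. The cultures had grown for 96 h at 28 °C in a minimal medium with cellulose as the carbon source. Both strains derive from QM6a and lack ku80, whose product acts in non-homologous end joining and whose loss is used to ease gene targeting in fungi. The parent is called ku80 here. The other strain also lacks sor4, described by the submitters as a transporter of the SOR cluster, the genes for sorbicillinoid pigments, and is called sor4 here. The series asks what loss of sor4 changes in light and in darkness. Of the 12 libraries, 2 came from ku80 in darkness, 4 from sor4 in darkness, 2 from ku80 in light and 4 from sor4 in light. Total counts ran from 7844524 in ku80 light replicate 2 to 12027855 in sor4 darkness replicate 4, and 8939 of 10879 rows had enough counts to be tested. The deposited table does not pair its identifiers with gene names, so genes are given by identifier and the row of sor4 itself could not be looked up by name.

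Light and darkness separated the libraries far more than the strain did. The first principal component of log2 CPM (counts scaled to a common library size) held 79.8% of the variance and placed the dark libraries between -74.5 and -67.0 and the light libraries between 67.8 and 76.9. The second component held 4.35% and spread libraries within groups, from 24.1 for replicate 1 to -38.4 for replicate 2 in ku80 light and from 24.1 for replicate 1 to -19.6 for replicate 3 in sor4 darkness. Between the ku80 light libraries, 334 genes were over 4-fold apart, against 46 to 59 for pairs of sor4 light libraries, 50 for the ku80 dark pair and 54 to 249 for pairs of sor4 dark libraries. As a check for a library deposited more than once, the counts of each pair within a group were compared; the chi-square per gene was between 7.12 and 81.5, and no pair was counted as 1 sample. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

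**Figure D1:**
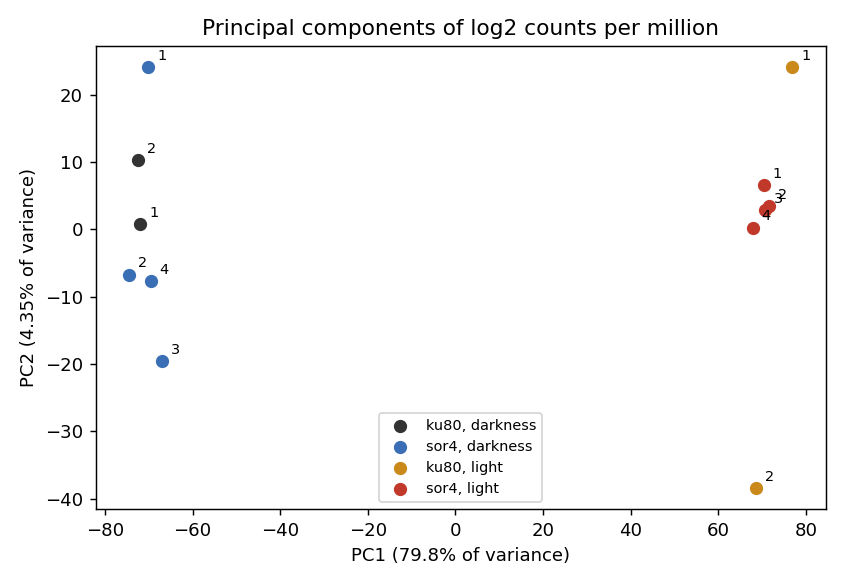
Principal components of log2 CPM over the 8939 genes tested, with 1 point per library, coloured by strain and light condition and numbered by replicate; both axes are component scores. The dark libraries lie between -74.5 and -67.0 on the first axis and the light libraries between 67.8 and 76.9, and on the second axis the ku80 light libraries lie at 24.1 and -38.4 and the sor4 dark libraries between -19.6 and 24.1.

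In darkness, 1 transcript was almost missing from the sor4 strain. TrE0662C stood at 4902 ± 1258 CPM (SD, n = 2) in ku80 and at 1.03 ± 1.55 CPM (SD, n = 4) in sor4, with 38841 and 64425 counts in the ku80 libraries and 1, 5, 1 and 39 counts in sor4 replicates 1 to 4. The pooled level was 4278-fold lower in sor4 (95% interval 3207 to 5843, for counting error alone), and the log2 fold change was -12.08 (SE 0.78, adjusted p = 0.00173, edgeR quasi-likelihood test). Replicate 4 gave 39 of the 46 sor4 counts of TrE0662C, and without it the log2 fold change was -14.18. TrG0659W fell from 149 ± 14.5 CPM (SD, n = 2) to 90.8 ± 1.5 CPM (SD, n = 4), a log2 fold change of -0.72 (SE 0.085, adjusted p = 0.00921). TrD0762C, named after its values were seen because 3 genes passed the test in all, fell from 169 ± 1.26 to 112 ± 4.00 CPM, with a log2 fold change of -0.59 (SE 0.065, adjusted p = 0.00677). All 3 genes were lower in each of the 4 sor4 libraries than in both ku80 libraries.

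Across the 8939 genes tested in darkness, 3 fell and 0 rose in sor4. At an unadjusted p under 0.05 there were 693 genes, and DESeq2 called 78, of which 63 were lower and 15 higher. For 6729 genes (75.3%) the 95% interval of the difference lay within 2-fold in either direction. In simulated counts with the same design, the test found 63 of 100 genes changed 2-fold and 91 of 100 changed 4-fold. These rates were found with 200 changed genes and overstate the power where few genes change. The call of TrE0662C held in every alternative run, while those of TrG0659W and TrD0762C ended without ku80 dark replicate 2, with only these 6 libraries in the fit and with the replicate number as a block, and that of TrG0659W also without sor4 dark replicate 4; the log2 fold changes there were -0.72 to -0.61 for TrG0659W and -0.60 to -0.56 for TrD0762C, close to those above. The count was 22 without ku80 dark replicate 1, 1 without ku80 dark replicate 2, 8 without sor4 dark replicate 1, 6 without sor4 dark replicate 2, 1 with only these libraries and 1 with the block. Where a ku80 library was left out, here and in the other comparisons, the remaining one was assumed to vary like the other groups. The main fit also gives each gene the same spread in all 4 groups, though libraries varied unequally. The chi-square per gene was 7.12 to 15.7 for sor4 light pairs, 21.6 to 81.5 for sor4 dark pairs and 30.3 for the ku80 dark pair. The spread used in darkness may thus be too small. With only the 6 dark libraries, the adjusted p of TrG0659W was 0.280 (edgeR).

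**Figure D2:**
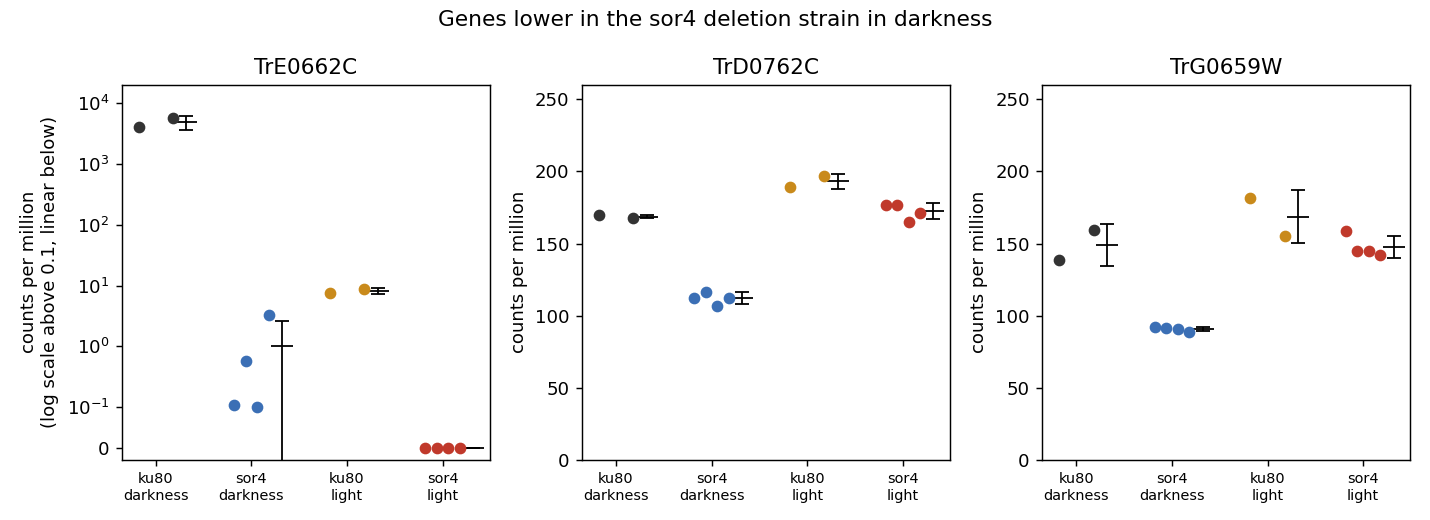
CPM of the 3 genes that passed the test between sor4 and ku80 in darkness, with 1 point per library in each strain and light condition; the bar beside each group is its mean with the SD (n = 2 for ku80, n = 4 for sor4). The axis of TrE0662C is logarithmic above 0.1 CPM and linear below, and its sor4 libraries lie at or under 3.34 CPM in darkness and at 0 in light.

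In light, TrE0662C was again missing from sor4. It had 78 and 70 counts in the ku80 libraries, or 8.12 ± 0.90 CPM (SD, n = 2), and 0 counts in each of the 4 sor4 libraries. Against a floor of 3 counts over the group, its level was at least 108-fold lower in sor4. With an adjusted p of 0.259 in edgeR it did not pass the test over all genes. It passed in DESeq2 (adjusted p = 0.00118), with the replicate number as a block (0.0376) and without sor4 dark replicate 4 (0.0123), and its adjusted p lay between 0.00118 and 0.667 across all alternatives. An exact test of 2 libraries against 4 cannot give a two-sided permutation p below 0.0667. The values of TrG0659W were 142 to 159 CPM in sor4 and 156 and 181 CPM in ku80, and those of TrD0762C were 172 ± 5.69 CPM (SD, n = 4) and 193 ± 5.49 CPM (SD, n = 2); neither passed the test.

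No gene passed the edgeR test between sor4 and ku80 in light, and the smallest adjusted p was 0.0965. At an unadjusted p under 0.05 there were 730 genes, DESeq2 called 48 (36 higher and 12 lower in sor4) and limma-voom called 2. The 95% interval lay within 2-fold for 6594 genes (73.8%). These include genes with 0 counts in all light libraries, such as TrE0665C, whose interval had no width and carries no information. In simulated counts the test found 57 of 100 genes changed 2-fold and 82 of 100 changed 4-fold. With 200 genes changed there, these rates overstate the power where few genes change. The count was 110 without ku80 light replicate 1, 14 without ku80 light replicate 2, 1 without sor4 dark replicate 4, 1 with only these libraries and 1 with the replicate number as a block; the gene called with the block, and without sor4 dark replicate 4, was TrE0662C. The one called with only these libraries was TrE0663W, named after its values were seen, which was higher in sor4 in light (log2 fold change 1.68, adjusted p = 0.259 in the main fit and 0.0193 there) and also passed in DESeq2 (8.68e-05).

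Light changed a large part of the transcriptome of ku80. Of the 8939 genes tested, 1772 rose and 2038 fell in light, and of these 769 rose and 1260 fell at least 2-fold, 346 and 784 at least 4-fold, and 91 and 356 at least 16-fold. TrG0832W fell from 539 ± 43.8 CPM (SD, n = 2) in darkness to 0 counts in light, 3294-fold against the floor of 3 counts over the group (adjusted p = 5.14e-08). TrB0435C fell from 446 ± 114.8 CPM to 0 counts, 2703-fold against the same floor (adjusted p = 1.03e-06). TrD1022C rose from 2 counts in darkness, both in replicate 1, to 300.4 ± 46.7 CPM in light (adjusted p = 2.70e-05), a ratio of 3169 with a 95% counting interval of 877 to 26178. TrF1202W rose from 0 counts to 51.6 ± 14.0 CPM, 367-fold against that floor (adjusted p = 0.00126). TrE0662C and TrE0391W were named after their values were seen. TrE0662C, the transcript missing from sor4, fell 618-fold from 4902 to 8.12 CPM (adjusted p = 9.54e-05), and TrE0391W rose from 25.2 ± 8.12 to 46865 ± 12288 CPM (adjusted p = 0.000489). The balance of all calls depended on the scaling: with library size alone, 2086 genes rose and 1790 fell, and 876 rose and 1193 fell at least 2-fold. DESeq2 called 4124 genes, and a fit of only the 4 ku80 libraries called 2330. In simulated counts the test found 48 of 100 genes changed 2-fold and 80 of 100 changed 4-fold.

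In the sor4 strain, light raised 2380 genes and lowered 2570 of the 8939 tested. At least 2-fold changes numbered 786 up and 1417 down, those of at least 4-fold 304 and 894, and those of at least 16-fold 67 and 360. TrE0671C fell from 1283 ± 152 CPM (SD, n = 4) in darkness to 3 counts over the 4 light libraries, a ratio of 17304 (95% counting interval 5921 to 83913, adjusted p = 2.34e-10). TrG1195C fell from 802 ± 141 CPM to 2 counts, both in replicate 4, a ratio of 16259 (4501 to 134260, adjusted p = 2.84e-10). TrE0391W, with a length of 180 nucleotides in the table, rose from 59.5 ± 87.1 to 39001 ± 3616 CPM, a log2 fold change of 9.35 (SE 1.17, adjusted p = 4.13e-05), which became 11.22 without sor4 dark replicate 3, where it stood at 189 CPM. It was the most abundant gene of all 6 light libraries, with 3.41% to 5.72% of their counts, and it had at most 0.0184% of the counts of a dark library. TrE0645C rose from 3 counts to 35.9 ± 2.85 CPM, a ratio of 472 (161 to 2289, adjusted p = 6.05e-09). With library size alone, 2571 genes rose and 2388 fell, and 834 rose and 1377 fell at least 2-fold. DESeq2 called 5111 genes and gave TrE0391W no adjusted p. In simulated counts the test found 73 of 100 genes changed 2-fold and 89 of 100 changed 4-fold.

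The light responses of the strains, measured in separate libraries, went the same way. In both strains 1573 genes rose, where independent lists of these sizes would share 472, and 1819 fell, where they would share 586. Both lists come from 1 fit with a common spread per gene, so low-spread genes pass more easily in both and these expected numbers are likely too low. In opposite directions 0 genes changed. Another 418 genes were called in ku80 alone and 1558 in sor4 alone, which does not by itself show a difference between the strains. The log2 fold changes correlated across the 8939 genes at Pearson r = 0.913 and Spearman rho = 0.885; genes are not independent replicates. The 686 genes that fell at least 4-fold in both strains, chosen on these libraries, gave 13.1% ± 0.77 of all counts in ku80 (SD, n = 2) and 11.4% ± 0.63 in sor4 (SD, n = 4) in darkness, and 0.761% ± 0.19 and 0.720% ± 0.017 in light. The 244 genes that rose at least 4-fold in both, chosen in the same way, went from 0.542% ± 0.073 to 10.8% ± 1.38 in ku80 and from 0.623% ± 0.063 to 9.87% ± 0.52 in sor4. TrE0391W is among them; without it the share in light was 6.0% ± 0.088 in ku80 and 5.90% ± 0.16 in sor4. By mean CPM, 50 genes were at 10 or more in darkness and under 0.5 in light in both strains, and 4 genes showed the opposite.

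**Figure D3:**
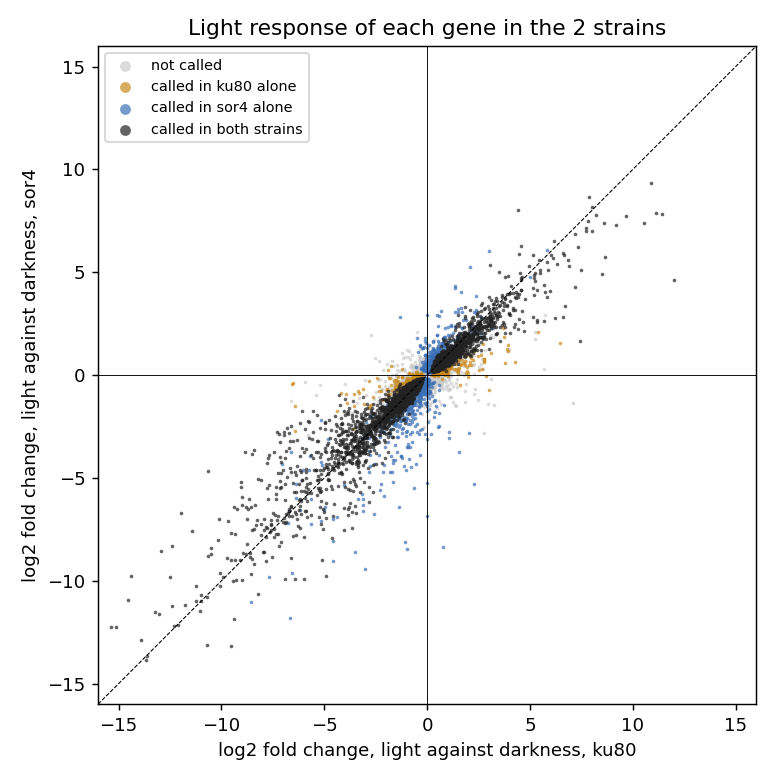
Log2 fold change of light against darkness in ku80 (horizontal axis) and in sor4 (vertical axis), with 1 point per gene for 8939 genes, coloured by the strains in which the gene was called; the dashed line marks equal change. Most points lie along the line (Pearson r = 0.913), and 0 genes were called in opposite directions.

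**Figure D4:**
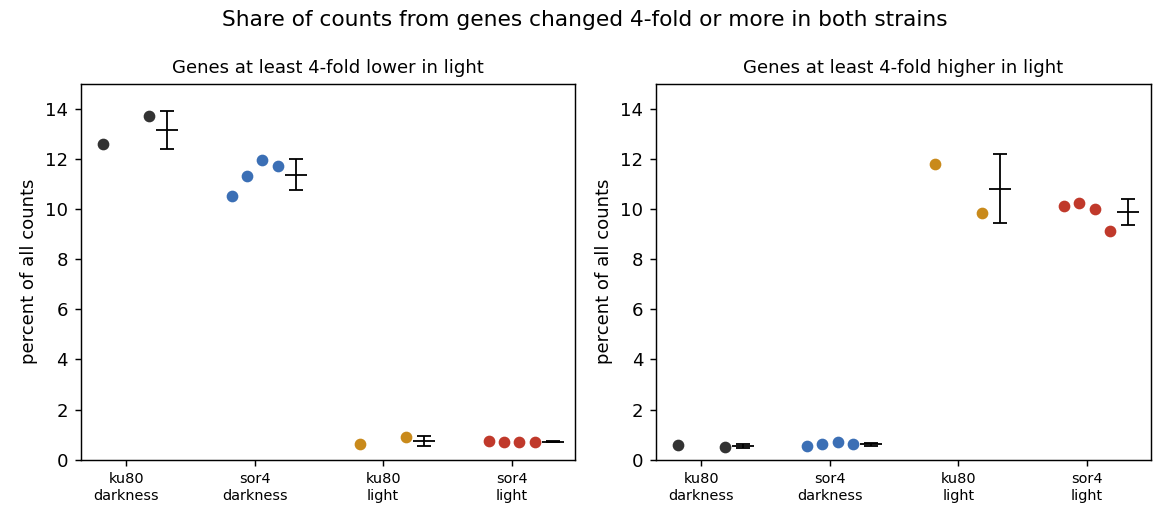
Percent of all counts per library from the 686 genes that fell and the 244 genes that rose at least 4-fold in light in both strains, with 1 point per library; the bar beside each group is its mean with the SD (n = 2 for ku80, n = 4 for sor4). The genes that fell held 11.4% to 13.1% on average in darkness and the genes that rose 9.87% to 10.8% in light, of which TrE0391W alone held 3.96% in sor4 and 4.81% in ku80; both sets were chosen on these libraries.

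Whether loss of sor4 acted differently in light and in darkness was tested as the difference of the strain effects. No gene passed edgeR's test, and the smallest adjusted p, 0.0759, belonged to TrE0663W. Its level in darkness was 665 ± 158 CPM (SD, n = 2) in ku80 and 215 ± 80.3 CPM (SD, n = 4) in sor4, and in light 34.4 ± 0.52 and 110 ± 14.8 CPM, so that every sor4 library was lower in darkness and higher in light. The difference of the log2 fold changes was 3.31 (SE 0.43). At an unadjusted p under 0.05 there were 589 genes, limma-voom called 0 and DESeq2 called 4. The 95% interval of the difference lay within 2-fold for 5560 genes (62.2%). In simulated counts the test found 25 of 100 genes with a 2-fold difference of effects and 76 of 100 with a 4-fold one. These rates, too, were found with 200 changed genes and are too high where few genes change. The count was 34 without ku80 light replicate 1, 1 with no filter on low counts, and 1 each without ku80 dark replicate 1, sor4 dark replicate 1 and sor4 dark replicate 2. TrE0663W passed the test in DESeq2, with no filter, and without sor4 dark replicate 1 or 2 or ku80 light replicate 1.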

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

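All tests of explanations in this part were chosen after the results they concern were seen. For the sor4 groups, 33 sets of 4 values (library totals, detected genes, shares of counts and the CPM of named genes) were checked for a library far from the others, with a check that marks about 1 set in 20 by chance. It marked 7, several of them near 0 counts. That rate assumes normally distributed values and does not hold near 0. There a single library with any count is marked whenever the others have none, so the 7 cannot be set against that rate. Of the 7, 4 concerned sor4 dark replicate 3. There TrE0391W stood at 189 CPM, against 2.80 to 28.3 in the other sor4 dark libraries, TrF1202W at 4.14 CPM (0 to 0.114) and TrD1022C at 4.34 CPM (0 to 0.108), while TrE0671C was lower, at 1056 CPM (1341 to 1387). TrE0662C stood at 3.34 CPM in sor4 dark replicate 4, against 0.101 to 0.572 in the other 3 libraries. In sor4 light replicate 4, TrB0435C stood at 0.280 CPM and TrG1195C at 0.187 CPM, against 0 in the other 3 libraries.

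TrE0663W was marked because sor4 and ku80 differed in opposite directions in darkness and in light in every library, with a difference of log2 fold changes of 3.31; the test of this difference gave an adjusted p of 0.0759. Such a pattern without overlap was seen in 78 of the 8939 genes (0.873%), where chance gives 0.889%.

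A candidate explanation for the missing reads of TrE0662C is that TrE0662C is the gene deleted in the sor4 strain. Of 7331 identifiers with at least 5 CPM in ku80 in darkness and 7108 in light, 1 had a sor4 mean under 1% of the ku80 mean in both conditions, TrE0662C, and 0 showed the reverse in either. The test would also be met by a gene whose transcription depends wholly on sor4, and this stays open without gene names. The 39 counts in sor4 dark replicate 4 were not explained.

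The 6 identifiers next to TrE0662C in table order, 3 on each side, had a median log2 fold change of -1.46 between sor4 and ku80 in darkness, though 0 of them passed edgeR's test; 1 of them, TrE0663W, passed in DESeq2 (adjusted p = 9.59e-05) and without sor4 dark replicate 1 (0.0214) or 2 (0.0393), over a range of 9.59e-05 to 0.766. In light, where the 6 stood 448-fold and 289-fold below the ku80 dark level in the ku80 libraries (median over the 6), their log2 fold changes between the strains ran from -1.26 to 1.68, with no common drop. A drop could hardly show there in TrE0665C, with 0 counts in all light libraries. The same holds for TrE0661W and TrE0664C, at no more than 1.38 and 2.56 CPM in light. Library scaling, where a factor moves all genes of a library alike, is argued against. Of 4141 such windows, 1 (0.0241%), this one, had a median as low, and the lowest one over 6 positions away was -0.60. This cannot decide on the ordinary spread of neighbourhoods whose genes vary together, as these 6 do, since windows were not matched for that. The 3 identifiers 7 to 9 positions after TrE0662C were also lower in each sor4 dark library, with mean log2 differences from ku80 of -0.76 to -0.35. None of the 3 passed edgeR's test in darkness (adjusted p = 0.256, 0.871 and 0.799). The nearest tested identifiers outside the 6, TrE0657C and TrE0668C, changed little in darkness (log2 fold changes 0.04 and -0.15). The spread between cultures whatever the strain cannot be told apart from an effect of the deletion, since an exact test of 2 libraries against 4 cannot give a p under 0.05. In darkness the 6 stood 39.5-fold, 4.06-fold, 1.99-fold and 2.42-fold below the ku80 level in sor4 replicates 1 to 4 (median over the 6), and an exact permutation test of their mean log2 CPM gave a two-sided p of 0.2, where 0.0667 is the smallest possible. Tests that take the spread from all 12 libraries gave smaller values, p = 0.0102 in fry and p = 0.0118 in camera with the estimated correlation of 0.55 between the 6 genes. These values cannot decide the question, since the 6 were picked after their dark values were seen. Part of the spread used there also comes from light libraries, where several of the 6 were near 0. Over all alternatives the median log2 fold change lay between -3.25, with the replicate number as a block, and -1.16, without sor4 dark replicate 1. With the block the strains were compared directly only within replicates 1 and 2, since ku80 has no replicate 3 or 4.

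The ku80 light libraries were over 4-fold apart in 70 genes of at least 10 mean CPM, 66 of them higher in replicate 2, against 0 to 10 genes in pairs of sor4 light libraries and 8 to 123 in pairs of dark libraries. RNA or reads of a dark culture in replicate 2 are argued against: 13 genes with at least 200 CPM in darkness and under 1 CPM in the other light libraries stood there at a median of 0.0182% of their dark level (1 of them at 41.3%), against 40.5% for the 24 genes raised in replicate 2 that light lowered in sor4. A day or batch shared by replicate 1 of both strains may contribute: the deviations of ku80 light replicate 1 correlated across genes at r = 0.0890 with those of sor4 light replicate 1 and at -0.0766 to 0.00545 with those of the other 3, which is too weak to decide, and the labels give no batch. No biological explanation was tested, since both libraries belong to 1 group.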

How the results depend on the processing

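The robust dispersion was chosen after the data were seen; all other alternatives were planned. For sor4 against ku80, 3 genes were called in darkness and 0 in light, with 0 for the difference of effects, and these counts moved most. DESeq2 called 78 in darkness, 48 in light and 4 for the difference, limma-voom called 2 in light, and dropping the filter on low counts gave 1 for the difference. Fits of only the groups compared had fewer libraries to estimate the spread and did not share the unequal spread of the other groups. Their counts were 1 in darkness, 1 in light and 2330 for light against darkness in ku80 (3810 otherwise). With each library left out in turn they were 1 to 22 in darkness, 0 to 110 in light and 0 to 34 for the difference; the highest were without ku80 dark replicate 1 in darkness and without ku80 light replicate 1 in the other two. The cause of these shifts was not tested beyond this.

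With the replicate number as a block, 1 gene was called in darkness, 1 in light, 0 for the difference, 3468 in ku80 and 4631 in sor4. Because ku80 lacks replicates 3 and 4, this fit compared the strains directly only within replicates 1 and 2. The numbers were not taken to pair the libraries: same-numbered dark and light libraries of sor4 deviated together at r = 0.0613, 0.00381, 0.0323 and 0.0621, those of ku80 at -0.0923, and 2 of the 4 sor4 dark libraries correlated best with their own number.

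Light against darkness called 2890 to 4124 genes in ku80 under the other alternatives and 4502 to 5206 in sor4 under all. With library size alone the balance of calls turned, from 1772 up and 2038 down to 2086 and 1790 in ku80 and from 2380 and 2570 to 2571 and 2388 in sor4. None of the named genes that were called changed direction. Genes called alike by light in both strains numbered 3392, and 2206 with only the groups compared. The correlation of the light responses ranged from 0.800 with no filter to 0.948 with the stricter filter, and was 0.813 without ku80 light replicate 1. TrE0662C kept its call in darkness in all 22 alternatives, with adjusted p up to 0.0454. No scaling moved the median log2 fold change of all genes by over 0.1. The alternatives planned for gene lists gave no value, since no list could be matched. Depth limits the folds against groups with 0 to 3 counts, which rest on the floor or have wide intervals.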

Other observations

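The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the libraries. Genes that lie next to each other in the table changed together in light. In sor4, 38 runs of at least 4 consecutive identifiers fell at least 2-fold, with 182 genes in all and 15 in the longest run, where 1000 shuffled orders gave 3.16 on average and 10 at most. Runs of genes that rose numbered 9, with 39 genes, against 4 at most in shuffled orders. The sources used here do not say whether the letters of the identifiers stand for chromosomes or whether the numbers follow their order along the genome.

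Genes within 50 positions of either end of a letter's series fell more often than the rest. Of 501 such genes tested, 40.9% fell at least 2-fold in light in sor4, against 14.4% of 8438 others (odds ratio 4.13, 95% interval 3.40 to 5.0), and 33.1% against 13.0% in ku80. The interval treats genes as independent and is too narrow, since neighbours changed together. Genes that rose at least 2-fold made up 11.6% and 8.63% in sor4. Circular shifts of the calls along the table, which keep neighbours together, gave as many fallen genes near the ends in 5 of 1000 shifts for sor4 and 4 of 1000 for ku80, and as many risen genes in 78 of 1000 for sor4. By letter, the share that fell in sor4 lay between 14.0% for A and 21.0% for F.

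The correlation of the light response between adjacent identifiers in sor4 was r = 0.327, and it was 0.193 at a distance of 2, 0.0834 at 10 and 0.0217 at 50. A chance order of the identifiers is argued against, since 0 of 1000 shuffled orders reached it and the highest was 0.0343. Reads shared or run on between neighbouring genes are argued against as the whole cause if W and C name the strands: 2245 pairs pointing away from each other (C then W) correlated at 0.508 (95% interval 0.476 to 0.538), against 0.315 for 3061 pairs on the same strand and 0.179 for 2297 pairs pointing towards each other. Shared control of adjacent genes may underlie the pattern, a hypothesis that was not tested here against a shared origin of adjacent genes.

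Other splits of the libraries were counted for the strain and light comparisons. Of the 35 ways to split the 8 sor4 libraries 4 against 4, 1 gave as many genes as light against darkness, the real one with 4950. The highest of the others was 0, but each of them mixed dark and light libraries, which puts the light difference into the spread. A share of 1 in 35 is under 0.05, yet it tests chance only if the libraries were separate cultures, which the labels do not say. For sor4 against ku80 the 15 splits of 6 libraries are too few for a share under 0.05. In darkness 5 of the 15 splits gave at least the real count of 3. The highest other gave 170 and set ku80 replicate 2 and sor4 replicate 1 against the remaining 4. A split that does not follow the strain thus gave more calls than the strain. Whether the dark libraries hold such a structure was not tested. In light the real count was 0, and the highest other split gave 14, with replicate 1 of both strains against the other 4 libraries.

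The 3 rows named for the mating type locus mat1-1 had 0 counts in all 12 libraries. QM6a is known to carry the other mating type.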
